A study of Homo sapiens with 21 samples.

How the data were processed

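ChIP-seq peak lists of FGFR1, H3K27ac, H3K4me3, Pol II S5P and FOXA1 from CAMA1 cells, and of FGFR1 after siNT or siFOXA1, were analysed as deposited, with 2 lists per group. Sequencing libraries were made from immunoprecipitated DNA after sonication and run on an Illumina NextSeq 500, per the labels' protocols. The build hg38 and the tools Bowtie2, SAMtools, Picard and MACS2 are named in the submitters' processing notes, which give neither versions nor the role of each tool. Peaks were called per library, since the authors deposited a list for each sample. Each row of the deposited lists gives a position, a score, a fold enrichment (a linear ratio over background), a -log10 p-value, a -log10 q-value and a summit. The deposited score was not used here. Peak names inside the deposited lists disagree with the labels on the replicate number of untransfected FGFR1, and the names of the FOXA1 lists give FOXA2. The labels were followed throughout.

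How the caller was run affects what the lists can show. In all 14 lists every deposited fold enrichment lay on a regular grid (tolerance 1.5e-05), and every -log10 p-value that could be checked was that of a Poisson count against a single mean. Each list therefore was called against a single background for the whole genome, with no visible correction for local copy number or input. That background, 2.11 to 4.33 fragments per position, serves here as the measure of depth, and no total read count was used. The Pol II S5P pileups had been scaled by 0.711 and 0.721 to a common background of 2.23; their own backgrounds were 3.14 and 3.09. In 11 of the 14 lists the highest pileup was exactly 400 fragments, so the strongest peaks may be truncated.

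Only chromosomes 1 to 22 and X were used, which left out 0.0227% to 2.74% of the rows of a list. Overlapping rows of a list were merged. A reproducible region is a merged stretch that holds a peak of both lists of a group with at least 1 bp of overlap. The gene table used here (GRCh38.p14, the same primary assembly as hg38) gives a start and an end for 19974 protein-coding genes and neither strand nor exons. The planned promoter window was therefore replaced by windows of 1 kb to each side of both ends of a gene, and an end with reproducible H3K4me3 was taken as the promoter-like end. Exons, introns and UTRs are not given, and the planned search for motifs was not analysed here because no genome sequence was used.

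Shares of overlap were compared with 1000 random placements of the regions, keeping width and chromosome, within 100 kb bins that hold a gene or a peak of any list. Genes and regions were compared by Fisher's exact test, two-sided, with odds ratios and 95% Woolf intervals, and strata were combined by the Mantel-Haenszel method. Shares carry 95% Wilson intervals, which cover counting error only. The numbers of peaks of the siNT and siFOXA1 lists were compared by an exact permutation test. Lost regions were in both siNT lists and in neither siFOXA1 list, gained regions the reverse, and the same counts were made for the 2 mixed pairings of the 4 libraries. The 13 gene lists (455 symbols, all matched) were fixed before the data were examined, as were the main tests, most of the alternative settings and the rule for named genes. Tests of loss by features other than FOXA1 were not among those fixed. Nor were the FOXA1 comparison within genes with Pol II S5P and the comparison of marked with unmarked gene ends. That rule took the 10 genes with the highest mean within-list percentile of fold enrichment at gene ends in untransfected FGFR1, up to 12 bound members of the luminal, FGF and ERK, and immediate early lists, the 8 leading lost, gained and retained gene ends and the 5 leading lost distal regions, with FOXA1 and FGFR1 themselves. Some genes are not reported here. TSC1, PIK3CA, AKT1, AKT2 and the EEF1A1 and PGK1 comparison with untransfected cells were chosen after their values were seen.

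Alternatives were a stricter threshold (-log10 q of at least 5), reciprocal overlap of 50%, each FGFR1 list left out in turn, windows of 500 bp and 3 kb, circular shifts, lists of equal length, strata by peak strength and position, another gene background, removal of the 8p11 and 11q13 spans and a comparison by replicate number. Removal of the crowded windows, restriction to H3K27ac, a gene background with Pol II S5P and the stricter threshold for the 8p11 and 11q13 spans were added after seeing the data.

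The overlaps, the loss at FOXA1 sites, the gene lists and the background were tested on simulated data, and the other steps were not. For the FGFR1 overlaps, 2 of 20 sets of 4000 regions without a planted overlap had p under 0.05, and a planted share of 41.1% was recovered as 40.7%. For loss at FOXA1 sites, a planted odds ratio of 2 was recovered with a median of 1.93. The true value lay in 98 of 100 intervals, 50 of them from sets without an effect. Each set used a single list for retained regions, so the rule over both lists of a group was not simulated. For the gene lists, 59 of 60 raised lists and 1 of 200 others were called. The background was recovered in 10 simulated lists to within 9.3e-05%. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.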

Results

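Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map FGFR1, a receptor tyrosine kinase for fibroblast growth factors, on the genome of CAMA1 cells. CAMA1 is an oestrogen receptor-positive breast cancer cell line that the labels describe as FGFR1-amplified. The same cells were profiled for H3K27ac (a mark of active promoters and enhancers), H3K4me3 (a mark of promoters), RNA polymerase II phosphorylated on serine 5 (Pol II S5P, found at the start of transcribed genes) and FOXA1 (a pioneer factor that opens chromatin for the oestrogen receptor). FGFR1 was profiled again after transfection with a non-targeting siRNA (siNT) or an siRNA against FOXA1 (siFOXA1), 72 h before collection. Cells were kept without estradiol for 48 h. Each of the 7 groups had 2 libraries with a peak list each, 14 lists in all, and the 7 inputs were not used here. The untransfected FGFR1 lists held 5341 and 13135 peaks on chromosomes 1 to 22 and X, and the other untransfected lists 154358 and 145991 (H3K27ac), 41399 and 38624 (H3K4me3), 18713 and 12267 (Pol II S5P), and 123582 and 127427 (FOXA1). The siNT lists held 6007 and 6594 FGFR1 peaks, the siFOXA1 lists 4332 and 5056. The lists give no read counts, but the background recovered from their p-values, in fragments per position, stands for depth. It was 3.40 and 3.50 for untransfected FGFR1, 2.19 and 2.19 for siNT, and 2.11 and 2.20 for siFOXA1. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so their spread may be technical. Peaks, regions and genes are the units of the tests, which describe these lists and not a population of cultures.

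The first comparison asked where FGFR1 lies relative to promoters, active chromatin, Pol II and FOXA1. FGFR1 peaks lay mainly at the marked ends of active genes. Of 4736 FGFR1 regions present in both untransfected lists, 72.7% lay within 1 kb of an end of a protein-coding gene, 96.1% overlapped H3K27ac, 95.3% H3K4me3, 83.1% Pol II S5P and 44.0% FOXA1. Randomly placed regions of the same widths gave 4.43%, 9.49%, 3.32%, 0.670% and 4.40%, so the observed shares were 16.4, 10.1, 28.7, 124 and 10.0 times the random ones (permutation p = 0.0020 for each, two-sided, the smallest that the placements can give). Over single lists, the share at gene ends was 63.9% ± 5.07 (SD, n = 2) and the share with Pol II S5P 70.6% ± 11.9. H3K27ac, H3K4me3 and Pol II S5P all covered 3816 FGFR1 regions (80.6%), and 49 (1.03%) carried none of the 4 other targets. Distal regions, away from both annotated ends of a gene, with H3K27ac and without H3K4me3, the usual make-up of an enhancer, numbered 118. H3K4me3 overlapped 83.7% of the distal FGFR1 regions, and only 36.4% of all H3K4me3 regions lay at gene ends. The count of 118 therefore does not show how often FGFR1 lies at enhancers. FOXA1 overlapped 47.6% of the 1295 distal FGFR1 regions and 42.7% of the 3441 at gene ends (odds ratio 0.822 for gene ends, 95% interval 0.723 to 0.935, Fisher exact p = 0.0028). The replicates were uneven: 93.1% of the peaks of replicate 1 were found in replicate 2 and 36.3% the other way, and replicate 2 alone would give 13135 regions. The ratio to random placement at gene ends was 7.72 with windows of 3 kb. With the 1 kb windows it was 16.2 for Pol II S5P, 6.97 for H3K4me3, 3.16 for H3K27ac and 2.09 for FOXA1, against 16.4 for FGFR1. No input was used, and the random placements were not confined to active chromatin. These overlaps and the gene comparisons below therefore cannot separate FGFR1 binding from unspecific signal at active promoters.

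**Figure D1:**
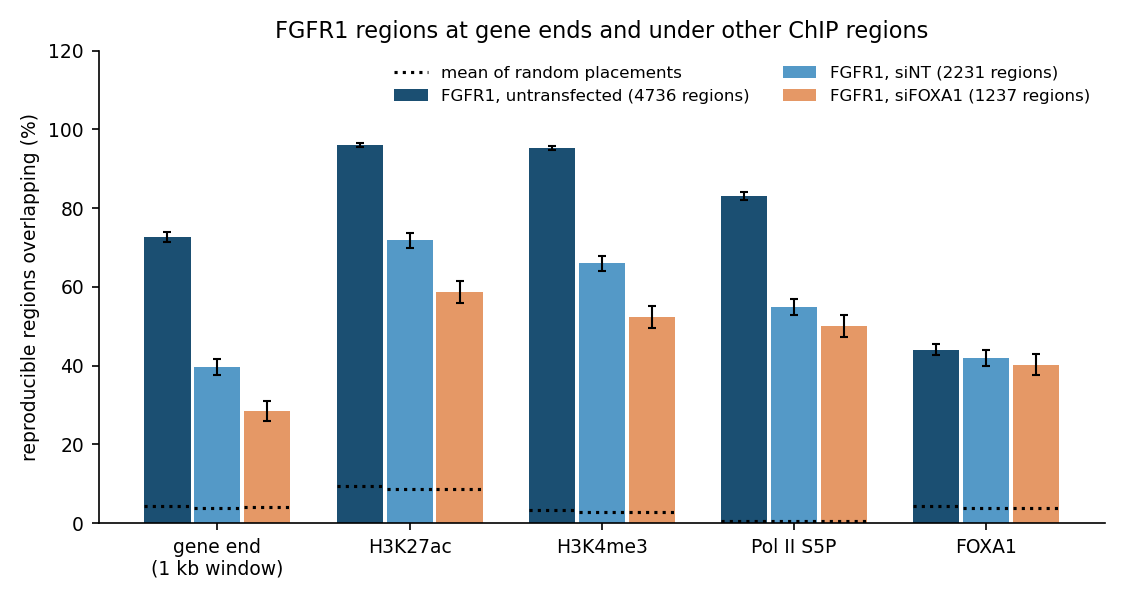
Share of reproducible FGFR1 regions (y axis, %) that overlap a gene end or a region of another target (x axis) in untransfected, siNT and siFOXA1 cells, with 95% Wilson intervals and dotted lines at the means of random placements. The share at gene ends was 72.7% in untransfected cells, 39.6% after siNT and 28.4% after siFOXA1.

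FGFR1 followed Pol II S5P more closely than FOXA1 from gene to gene. Of 13303 genes with H3K4me3 at an end, 29.9% carried FGFR1 at that end. The share was 47.6% where Pol II S5P was also found (7729 genes) and 5.27% where it was not (5574 genes), an odds ratio of 16.3 (14.4 to 18.5). It was 40.7% with FOXA1 (5360 genes) and 22.6% without (7943 genes), an odds ratio of 2.35 (2.18 to 2.54, Fisher exact p = 1.1e-109). Among genes with both H3K4me3 and Pol II S5P, FGFR1 was found at 53.6% of those with FOXA1 and 41.6% of those without, an odds ratio of 1.62 (1.48 to 1.78). Over all 19974 protein-coding genes the odds ratio was 36.1 (31.9 to 40.8) for Pol II S5P and 3.87 (3.60 to 4.16) for FOXA1.

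The strongest FGFR1 peaks at gene ends were at ZBTB7B, KDM3B and KMT2A. ZBTB7B, a zinc-finger transcription factor, led with the authors' fold enrichments of 37.3 and 43.5 in the 2 lists (chromosome 1, 155017276 to 155017894, hg38). The histone demethylase gene KDM3B followed with 33.7 and 39.1 (chromosome 5, 138352388 to 138353373), and the histone methyltransferase gene KMT2A with 30.7 and 37.5 (chromosome 11, 118436085 to 118436553). RHBDD2, VPS28, CCDC106, ING3, RAPGEF1, INKA2 and CCND1 completed the first 10. CCND1, the cyclin D1 gene, stood at 21.6 and 27.8 (chromosome 11, 69637806 to 69641613) inside the 11q13 span. CCND1, ZBTB7B, VPS28 and INKA2 lay in 1-Mb windows crowded with FGFR1 peaks of transfected cells, where copy number can raise peak calling. All 10 carried H3K4me3 and H3K27ac, and KMT2A and RAPGEF1 had no reproducible Pol II S5P there. Fold enrichment is the authors' own value; it ranked peaks within a list, and values of different lists stand side by side only as description.

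Growth signalling, ribosomal and stress genes carried FGFR1 more often than other genes with H3K4me3, and luminal oestrogen receptor genes did not pass that test. Of 13 gene lists fixed beforehand, 8 passed at an adjusted p of 0.05 (Fisher exact test, two-sided, Benjamini-Hochberg over the lists). FGFR1 was found at 50 of 76 ribosomal protein genes (65.8% against 29.7% of other marked genes; odds ratio 4.56, 2.84 to 7.34; Fisher exact adjusted p = 2.03e-09). It was found at 18 of 27 heat-shock and unfolded protein response genes (odds ratio 4.72, 2.12 to 10.5), 16 of 26 immediate early genes (3.77, 1.71 to 8.31), 20 of 36 FGF and ERK signalling genes (2.95, 1.53 to 5.69), 22 of 40 RNA processing genes (2.88, 1.54 to 5.38) and 20 of 39 chromatin regulators (2.48, 1.32 to 4.65). The lists of genes at 8p11 and 11q13 passed as well, with 17 of 20 genes at 8p11 (13.4, 3.91 to 45.6) and 7 of 10 at 11q13 (5.49, 1.42 to 21.2). The luminal list had 13 of 40 (1.13, 0.583 to 2.20; Fisher exact adjusted p = 0.791) and the cell cycle list 9 of 38 (0.728, 0.345 to 1.54; adjusted p = 0.568). The lists of other cell types did not pass: 1 of 15 basal or mesenchymal, 0 of 10 haematopoietic and 2 of 7 neuronal or hepatic genes with H3K4me3 were bound, with adjusted p of 0.066, 0.056 and 1. Tested against genes that also carry Pol II S5P, a background chosen after seeing the data, 5 lists passed, and RNA processing (odds ratio 1.62), chromatin regulators (2.09) and 11q13 (6.62) did not. With replicate 2 alone 5 lists passed, without immediate early genes (2.62), chromatin regulators (2.08) and 11q13 (5.60). The 11q13 call also ended with a window of 3 kb (3.91).

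**Figure D2:**
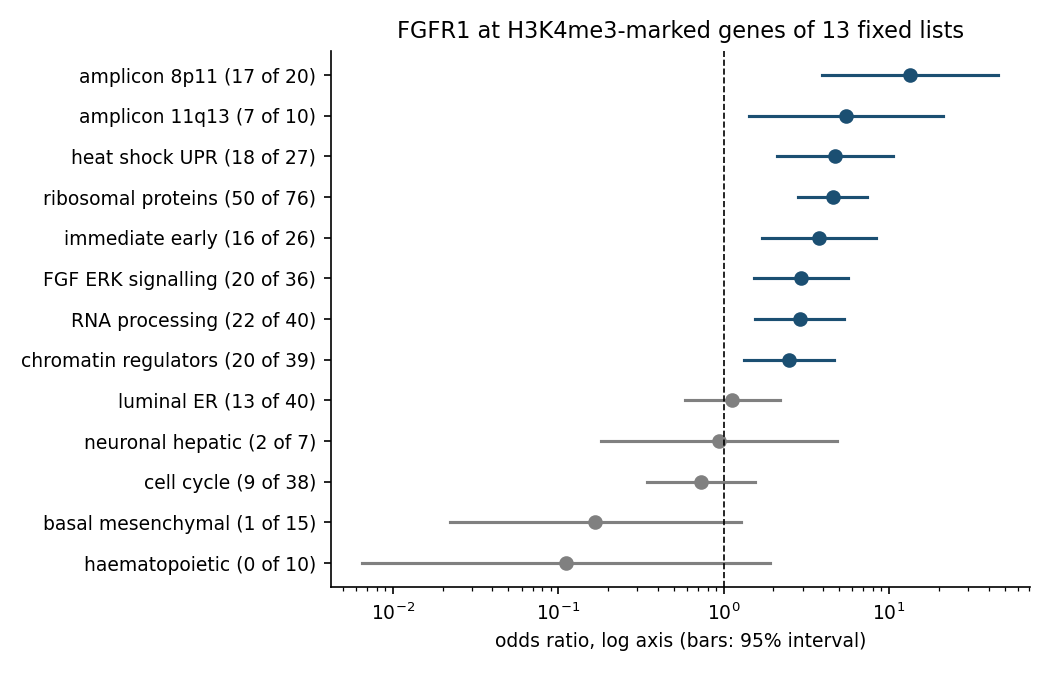
Odds ratio (x axis, log scale, with 95% intervals) of a reproducible FGFR1 region at the H3K4me3-marked end of the genes of 13 fixed lists, against all other H3K4me3-marked genes, with bound and tested members beside each name. Blue points passed at an adjusted p of 0.05, and ribosomal protein genes had 50 of 76 members bound and luminal genes 13 of 40.

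Among immediate early genes, which respond within minutes to growth factors, JUNB had the strongest FGFR1 peak (fold enrichments of 18.9 and 34.4), followed by JUND (16.4 and 17.3) and DUSP1 (12.5 and 23.8), and IER5, MYC, SRF, KLF10, IER3, EGR1, MCL1, ZFP36L2 and KLF4 came next. In the FGF and ERK list the adaptor gene SHC1 (10.0 and 15.1), MYC (9.33 and 16.0), the receptor gene FGFR4 (10.0 and 13.3) and the phosphatase gene PTPN11 (10.5 and 12.2) followed CCND1. FGFR1 itself carried a peak at its H3K4me3-marked end (10.0 and 10.4; chromosome 8, 38468317 to 38468904), and IER3, EGR1, MAP2K2, BRAF and FRS3 came after it. Luminal genes with FGFR1 were led by the demethylase gene KDM4B (16.6 and 24.9), the ETS factor gene ELF3 (8.87 and 14.2) and the keratin gene KRT19 (8.87 and 9.55). KRT8 and KRT18, which share a region, SPDEF, CELSR2, GRHL2, STC2, SIAH2 and IGFBP4 were also bound. The FOXA1 gene carried FGFR1 at its end in both untransfected lists (5.0 and 7.99; chromosome 14, 37595220 to 37595683).

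The second comparison asked whether FOXA1 knockdown changes where FGFR1 is found. The level of FOXA1 after transfection was not analysed here. FGFR1 peaks were fewer in both siFOXA1 lists than in both siNT lists, at 4694 ± 512 against 6300.5 ± 415 (SD, n = 2 each; ratio 0.745; exact permutation p = 0.333, two-sided, the smallest that 2 against 2 allows). Reproducible regions numbered 1237 after siFOXA1 and 2231 after siNT, a ratio of 0.554. Most peaks of a transfected list were absent even from the other list of its group. Only 37.9% and 34.7% of siNT peaks and 29.3% and 25.1% of siFOXA1 peaks were found there. Of the siNT regions, 774 (34.7%) had no peak in either siFOXA1 list and are called lost. Of the siFOXA1 regions, 207 (16.7%) had no peak in either siNT list and are called gained. All 4 transfected lists shared 811 siNT regions, and 646 more were found in 1 siFOXA1 list. When 1 library of each condition was paired against the others, 244 and 292 regions were specific to a pair in the first mixed split, and 313 and 262 in the second. The 3 possible splits cannot give a share under 0.05. With a threshold of -log10 q of at least 5, lost regions numbered 451 and gained regions 27. With the FGFR1 lists cut to equal length, lost regions numbered 555 and gained regions 236. With a single siNT list as reference, lost regions numbered 4396 (replicate 2) and 3795 (replicate 1), and with a single siFOXA1 list gained regions numbered 3030 and 2368, since regions then need no second list. Gained regions numbered 323 without siNT replicate 1 and 316 without siNT replicate 2.

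Lost and gained regions differed in where they lay. Between 46.8% and 60.6% of the peaks of each transfected list fell into 32 windows of 1 Mb that each held over 10 times the mean number of peaks of these 4 lists together (48.5% and 46.8% in siNT, 56.7% and 60.6% in siFOXA1). These crowded windows, chosen after seeing the data from the same lists, which raises their share there, lie mainly on 8p, 11q and 1p. Outside them 524 regions were lost (37.0% of 1418) and 17 gained (2.82% of 602), against 77 and 45, and 60 and 82, in the mixed splits. Inside them 250 were lost and 190 gained, about as many as in the mixed splits there (167 and 247, and 253 and 180).

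**Figure D3:**
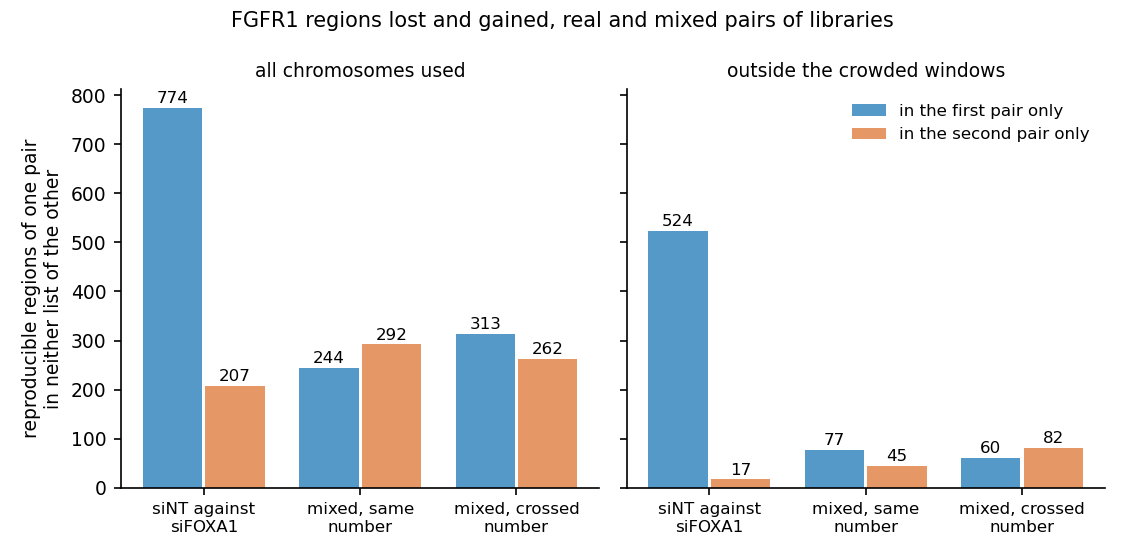
Number of reproducible FGFR1 regions of a pair of libraries found in neither library of the other pair (y axis), for siNT against siFOXA1 and for the 2 mixed pairings (x axis), over all chromosomes used and outside the crowded windows (blue: first pair, orange: second). Outside the crowded windows 524 regions were specific to siNT and 17 to siFOXA1, and the mixed pairings gave 45 to 82.

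The strongest regions lost at gene ends were at RBBP5, a subunit of histone H3K4 methyltransferases (siNT fold enrichments of 9.73 and 12.5; chromosome 1, 205122228 to 205122551), TTC9B (10.0 and 10.7) and the oxytocin receptor gene OXTR (8.79 and 13.5). The Mediator subunit genes MED23 (10.0 and 9.40) and MED13L (9.10 and 9.40) and the TAF6L gene of a transcription coactivator complex (10.0 and 9.08) followed, with FAM171A2 and DPH7. Distal lost regions were nearest to TLR8, TMEM63B, RFX2, EXOC4 and GGA3, and 4 of these 5 were outside H3K4me3 or H3K27ac or both, the exception being the TLR8 region. Gained regions at gene ends included MAP2K7 (siFOXA1 fold enrichments of 7.07 and 5.32) and SCAMP3 (5.47 and 5.63), with ZMAT4, NR2C2, CDK4, PPP1R16A and KCND3. SCAMP3, ZMAT4, PPP1R16A and KCND3 lay in crowded windows, and SCAMP3 and PPP1R16A also carried another siNT region at an end. Retained regions were led by EEF1A1 (81.6 and 81.1 in siNT) and ZBTB7B (70.3 and 74.9), then PGK1, KDM3B, CCDC106, ATMIN, RFX7 and TPBGL. The strongest FGFR1 peak within the FOXA1 gene stood at 6.28 and 5.33 in the siNT lists, and no peak was listed within the gene in either siFOXA1 list. Of fixed-list genes with a reproducible siNT region, siFOXA1 regions were found at 2 of 7 ribosomal protein genes (RPL10A and RPS3), 4 of 10 FGF and ERK genes (CCND1, FGFR1, MYC and SHC1), 4 of 9 immediate early genes (DUSP1, JUNB, KLF10 and MYC) and 1 of 5 luminal genes (KDM4B). These subsets were not tested against each other.

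FGFR1 was lost slightly less often where FOXA1 had been found in untransfected cells. Of 934 siNT regions at FOXA1 sites, 299 (32%) were lost, against 475 of 1297 elsewhere (36.6%), an odds ratio of 0.815 (0.682 to 0.974, Fisher exact p = 0.024, adjusted p = 0.036 over 6 features). Of these features only FOXA1 had been fixed for a test beforehand. Regions with Pol II S5P were lost less often (28.8% against 41.8%, odds ratio 0.564, 0.473 to 0.673, Fisher exact adjusted p = 6.07e-10), as were regions also bound by FGFR1 in untransfected cells (27.1% against 45.8%, odds ratio 0.440, 0.368 to 0.526). Regions with H3K27ac were lost more often (36.3% against 30.6%, odds ratio 1.29, 1.06 to 1.57, Fisher exact adjusted p = 0.023). Gene ends (odds ratio 1.04, 0.870 to 1.24) and H3K4me3 (0.864, 0.720 to 1.04) did not pass. Single siNT peaks gave another picture when their detection in siFOXA1 lists was divided by that in the other siNT list, a measure set before its result was seen only for FOXA1. It was 0.664 and 0.658 with Pol II S5P against 0.716 and 0.711 without, 0.591 and 0.604 with H3K4me3 against 0.870 and 0.830 without, 0.613 and 0.604 with H3K27ac against 0.873 and 0.872 without, and 0.681 and 0.679 with FOXA1 against 0.692 and 0.684 without. Outside the crowded windows it was 0.580 and 0.586 with Pol II S5P against 0.549 and 0.549 without, 0.551 and 0.558 with H3K4me3 against 0.633 and 0.620 without, 0.534 and 0.537 with H3K27ac against 0.708 and 0.711 without, and 0.585 and 0.595 with FOXA1 against 0.556 and 0.555 without. The FOXA1 result ended under several settings: the odds ratio was 1.02 (0.840 to 1.25) with a reciprocal overlap of 50%, 0.843 with -log10 q of at least 5, 0.943 (0.755 to 1.18) outside the crowded windows and 0.877 within H3K27ac. With a single siNT list it was 0.459 (without replicate 1) or 0.525 (without replicate 2).

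FGFR1 peaks were dense over the 8p11 and 11q13 spans, where copy number was not measured here. Over the span of the 8p11 genes (chromosome 8, 37695782 to 39105261), which includes FGFR1, untransfected FGFR1 peaks per Mb were 17.7 and 36.7 times those of the rest of the genome. It held 48 and 241 untransfected, 209 and 260 siNT and 172 and 218 siFOXA1 peaks. Elsewhere, FGFR1 peaks per Mb were 1.92 and 4.65 in untransfected cells, 2.05 and 2.23 after siNT and 1.44 and 1.68 after siFOXA1. The ratio was 72.4 and 82.8 after siNT and 84.7 and 92.3 after siFOXA1. For the other targets it was 48.1 and 41.4 (Pol II S5P), 4.96 and 5.41 (H3K27ac), 3.65 and 4.06 (H3K4me3) and 4.69 and 4.56 (FOXA1). At 11q13 (chromosome 11, 69048932 to 71253234), around CCND1, it was 15.8 and 23.8 for untransfected FGFR1, 50.9 and 56.4 for siNT and 77.5 and 76.3 for siFOXA1. With -log10 q of at least 5 the untransfected means moved from 27.2 to 16.1 at 8p11 and from 19.8 to 11.9 at 11q13. Outside all crowded windows, H3K27ac overlapped 97.2% of untransfected, 81.5% of siNT and 71.8% of siFOXA1 FGFR1 regions; inside them the shares were 87.2%, 55.2% and 46.5%.

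**Figure D4:**
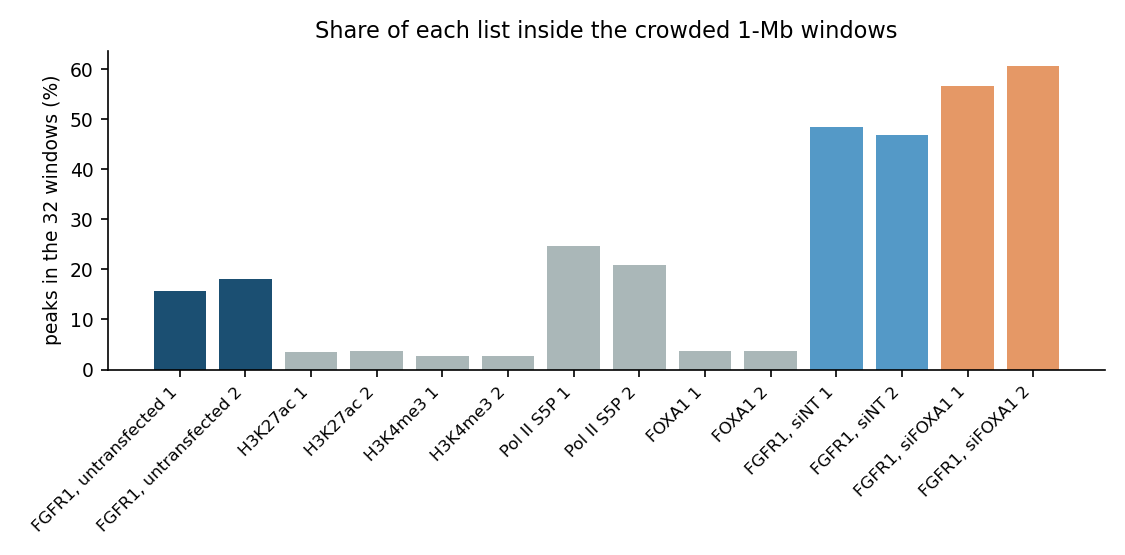
Share of the peaks of each list (y axis, %) that lie in the 32 1-Mb windows chosen as crowded in the 4 transfected lists, for the 2 replicates of each group (x axis). The share was 15.8% and 18.0% for untransfected FGFR1, 46.8% to 60.6% for the transfected lists, 24.7% and 20.9% for Pol II S5P and 2.72% to 3.77% for H3K27ac, H3K4me3 and FOXA1.

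TSC1, a growth suppressor of the mTOR pathway, carried a series of narrow FGFR1 peaks along its body in transfected cells. The siNT lists held 16 peaks on average outside H3K27ac in the gene (chromosome 9), the siFOXA1 lists 15, the Pol II S5P lists 14.5 and the FOXA1 lists 10, and neither untransfected FGFR1 list held any. PIK3CA, which encodes the catalytic subunit of PI3-kinase, held 16 in the Pol II S5P lists, 5 after siNT, 0.5 after siFOXA1 and 4.5 in the FOXA1 lists. AKT2 and AKT1 held 8 and 6 in the Pol II S5P lists and none after siNT. No gene outside the crowded windows had more than 1 such region in untransfected FGFR1. At EEF1A1 the transfected FGFR1 lists had fold enrichments of 81.1 to 83.6 and the untransfected lists no peak (replicate 1) or 6.0 (replicate 2). At PGK1 these were 41.0 to 80.4 and no peak or 14.9.

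**Figure D5:**
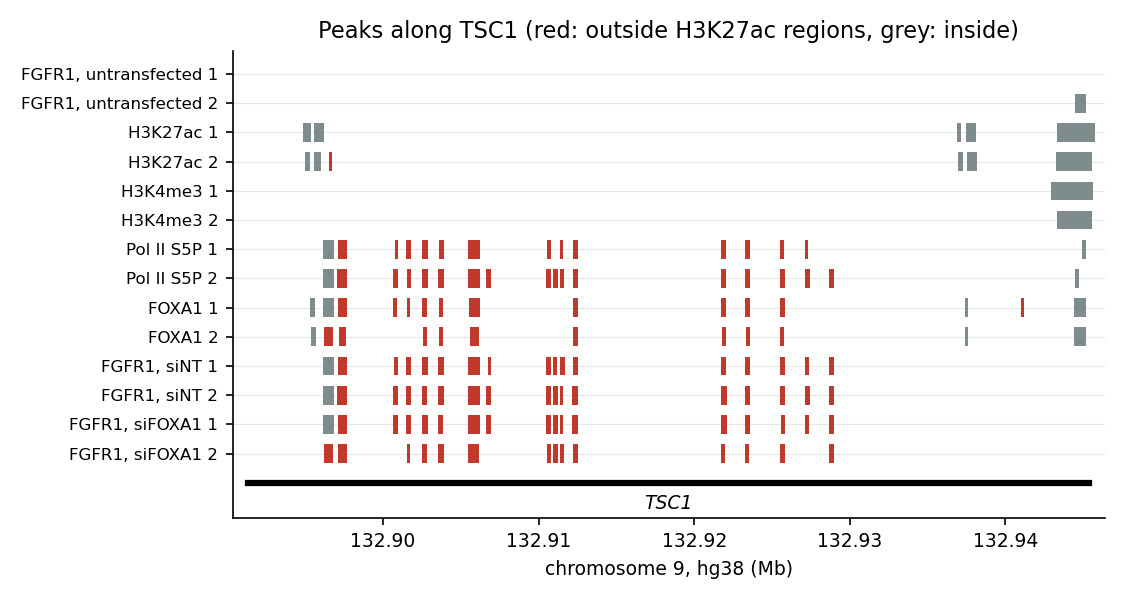
Peaks of the 14 lists (rows) along TSC1 on chromosome 9 (x axis, Mb, hg38), with red blocks outside and grey blocks inside reproducible H3K27ac regions and the annotated gene as a black bar. The transfected FGFR1, Pol II S5P and FOXA1 lists share narrow red blocks that the untransfected FGFR1 lists lack, where the means were 16 after siNT and 0 in untransfected FGFR1.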

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

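The tests of copy number and of DNA copies at TSC1, PIK3CA, AKT1 and AKT2, of a preference of FGFR1 alone, of depth and of detection by H3K27ac were chosen only after the results were seen, as were the crowded windows, the 4 genes and the bound by which the loss at FOXA1 sites, a test fixed beforehand, was weighed here.

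Peaks were also listed on unplaced scaffolds, which the comparisons did not use, in every list; a count above 0 drew attention to them. They numbered 44 and 53 for untransfected FGFR1, 24 and 28 for H3K27ac, 75 and 71 for H3K4me3, 84 and 71 for Pol II S5P, 55 and 61 for FOXA1, 96 and 102 for siNT and 107 and 108 for siFOXA1. No input list was used, so no control level stands beside these counts.

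TSC1, PIK3CA, AKT1 and AKT2 carried separate narrow peaks outside H3K27ac in the transfected FGFR1, Pol II S5P or FOXA1 lists. DNA copies of transcripts or vectors could give such peaks whatever the antibody, and this stays open: 8 of 19 siNT regions in these genes were in both FOXA1 lists, against 63 of 244 others outside H3K27ac (odds ratio 2.09, 0.804 to 5.43). The H3K4me3 and untransfected FGFR1 lists held no such peak in the 4 genes, so DNA copies would have to differ between libraries. Copy number gain of the loci, which would act in every list, is argued against for these 4 genes. The untransfected FGFR1 lists held 0 peaks outside H3K27ac in the 4 genes (upper Poisson bound 3.69). The siNT lists, of lower background, held 42, and AKT1 and AKT2 had none in any FGFR1 list. The choice of the genes from the siNT and Pol II S5P lists can raise the 42. It does not account for a count of 0 in untransfected lists of higher background. FGFR1 lists also differed at 8p11, but both untransfected lists held peaks there (48 and 241, against 209 and 260 after siNT). The share of siNT regions in both Pol II S5P lists (84.2%) was set aside because the genes had been chosen from those lists. Exon positions were not used here, and the design gives no biological explanation to test.

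FGFR1 peaks crowded into 32 windows that include 8p11 and 11q13. A preference of FGFR1 alone is argued against by Pol II S5P, whose peaks per Mb at 8p11 were at least 41.4 times those elsewhere. Copy number gain called against a single genome-wide background could give this crowding: siNT peaks outside H3K27ac and gene ends were more frequent inside the windows than elsewhere (odds ratio 2.41, 2.24 to 2.59). The odds ratio was 10.7 and 16.7 for untransfected FGFR1, 16.7 and 32.1 for Pol II S5P and 1.62 and 1.2 for siFOXA1, but 0.591 and 0.601 for FOXA1 and 0.769 (0.617 to 0.960) and 0.799 (0.634 to 1.01) for H3K4me3, and copy number was not measured here, so it stays open with any other biological explanation, none of which was tested.

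Fewer FGFR1 regions were found after FOXA1 knockdown. More frequent loss at sites with FOXA1 in untransfected cells is argued against by the odds ratio of 0.815 (upper bound 0.974). It was 0.943 outside the crowded windows (upper bound 1.18). Under reciprocal overlap it was 1.02 with an upper bound of 1.25, so a modest excess of loss stays possible there. The level of FOXA1 after transfection was not analysed here, so a role of FOXA1 in the loss is not excluded. Depth stays open: the background was 2.20 in siFOXA1 replicate 2, no lower than the 2.19 of each siNT list, but 2.11 in replicate 1, which had the fewest peaks (4332). Lower enrichment of the siFOXA1 libraries could give the difference at sites with and without FOXA1. Outside the crowded windows, detection relative to the other siNT list was 0.590 and 0.555 there, 1.06 times apart. It was 0.535 with and 0.710 without H3K27ac, 1.33 times apart. Peaks without H3K27ac were less often found in the other siNT list (24.2% and 20.5%, against 58.3% and 53.4%). Peaks with FOXA1 were also found there more often (57.6% and 55.4%) than peaks without FOXA1 (41.0% and 35.2%). Lower enrichment need not act alike on peaks so unlike, so neither the H3K27ac nor the FOXA1 test can decide. Lower enrichment and an effect of the knockdown both stay open. The 3 splits cannot give a share under 0.05; the real split gave 981 regions specific to either pair and the highest other 575.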

How the results depend on the processing

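Settings that leave out the crowded windows, keep only H3K27ac regions, use genes with Pol II S5P as background or apply the threshold to the 8p11 and 11q13 spans were chosen only after the results were seen. Of 196 values under alternatives, 162 were counted as unchanged, 15 moved, 6 reversed, 11 were weaker and 2 stronger. Unchanged means the same direction and side of the threshold at any size or, for counts and densities, a move within a set limit. Among the unchanged are 3381 FGFR1 regions with reciprocal overlap, against 4736, and 1120 lost regions without siFOXA1 replicate 1, against 774. FGFR1 overlaps with gene ends and the 4 other targets passed under each alternative run (gene-end share 60.3% to 77.4%). Leaving out a replicate raises counts by construction, since a region then needs no second list or need be absent from only 1 opposing list: FGFR1 regions 5341 to 13135, lost 1074 to 4396, gained 316 to 3030; lists past the threshold numbered 5 to 8, and the luminal odds ratio was 0.841 to 1.14. With -log10 q of at least 5, lost regions numbered 451, gained 27, the odds ratio of loss at FOXA1 sites was 0.843 and the 11q13 ratio 11.9. That odds ratio was 1.02 with reciprocal overlap, 0.943 without the crowded windows and 0.877 within H3K27ac; without the crowded windows gained regions numbered 17, and the 11q13 list (0.832) kept 1 member and the 8p11 list none, so these 2 lists decide nothing there. With the Pol II S5P background 5 lists passed, with basal genes at 1.10 on 2 members and neuronal or hepatic genes at 3.31 on 1; with all genes as background the cell cycle list had 1.21. Apart from the replicates left out, the cause was not tested. Replicate numbers did not pair the libraries (26.0% and 23.6% of siNT peaks found in the siFOXA1 list of the same number, 26.2% and 23.8% in the other); compared by number, lost peaks summed to 9484, gained to 6280, the peak ratio was 0.744 and the odds ratio of loss 0.490. Motifs were not run, since no genome was used. Peak lists hold no signal below the threshold, so a region absent from a list may still be bound weakly, and lost regions fell to 451 at the stricter threshold; depth limits how far siNT lists (2.19) compare with untransfected ones (3.40 and 3.50).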

Other observations

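The Pol II S5P background for gene lists and the comparison of transfected with untransfected lists were chosen only after the results were seen. The comparison of marked with unmarked gene ends was not among the tests fixed beforehand.

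FGFR1 kept to the H3K4me3-marked side of genes. Of 10789 genes longer than 5 kb with H3K4me3 at 1 end, 3018 (28.0%) carried FGFR1 at the marked end and 4 (0.0371%) at the other, against 6087 and 121 for Pol II S5P and 4103 and 832 for FOXA1. Among genes with both H3K4me3 and Pol II S5P, FGFR1 was found at 18 of 23 FGF and ERK genes (odds ratio 3.98), 18 of 23 heat-shock genes (3.98), 16 of 20 immediate early genes (4.42), 50 of 75 ribosomal protein genes (2.22) and 17 of 17 genes at 8p11 (38.7), each past an adjusted p of 0.05.

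Transfected and untransfected FGFR1 lists differed widely. Of the siNT regions 59.3% were among the untransfected regions, and 27.3% of the untransfected regions were among the siNT regions, 13.8% among the siFOXA1 regions. In all 4 transfected lists and neither untransfected list, 83 siNT regions were found, 46 of them in the crowded windows and 14 in TSC1. PIK3CA, AKT1 and AKT2 held no peak in siFOXA1 replicate 2, so none of these regions lay there. Transfection and library batch were not separated by the labels.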
